A study of Mus musculus with 4 samples.

How the data were processed

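RNA sequencing of female mouse neural stem cells was analysed in 4 libraries, 2 from Smchd1-deleted and 2 from control cells. Per the labels' protocols, lines were established from E14.5 embryos, part of each line was transduced with a Cre and puromycin retrovirus, selected from the day after and harvested 7 days after transduction, and the remainder was left untransduced. Deletion is therefore confounded with transduction and selection. The series' design text speaks of 3 lines per genotype; further lines were not analysed here.

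The authors deposited raw counts per gene as whole numbers, with 3 columns per library, 12 in all: all aligned reads, reads of a first parental genome and reads of a second. Per the submitters' processing notes the build was mm10 and the tools included bcl2fastq, TopHat2 2.0.12 and edgeR. How reads were split by genome, how they were counted and whether strand was used are not given in the sources used here. The columns do not name their genomes. The first was read as 129 and the second as Cast because the labels place the Xist deletion on the 129 X, and at least 99.57% of allele-assigned Xist counts were in the second. The table held 25965 entries, 1091 of them X-linked, with 66 repeats of a symbol already used. Coordinates are those of the table, and 87.56% of its symbols were found in the GENCODE M21 annotation, 99.47% of those at an overlapping position.

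Group came from the labels, and line from numbers in the column names, written here as A and B. Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3, with genotype as the only term, as fixed before the data were examined. Tests covered total counts, Cast counts, 129 counts (library sizes from the sum of both alleles) and the Cast to 129 ratio (an allele by genotype term with library as a block). The same-numbered libraries are parts of the same cell line, which pairs them. Their deviations from the group means correlated across 14860 genes at r = 0.72, where genes are not independent replicates, and the first principal component, with 58.4% of the variance, separated the lines. The fit with line as a block, planned as an alternative, is therefore printed beside each result whose call it changes. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 46.03 between controls and 74.67 between deleted libraries). With 2 libraries per group and 2 lines, p-values measure the spread of these cultures only. The blocked fit of the ratio had a dispersion of 0.000337, so its errors are close to counting error, and exact tests within a line, 1 library against 1, cover counting error only.

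Gene lists, 20 in all, were fixed before the data were examined, and those with at least 3 tested members, with all X-linked genes on total, Cast and 129 counts, made 17 camera tests (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the 17). They were Hox, protocadherin alpha, beta and gamma, the Snrpn and Igf2r clusters, other imprinted genes, known escape genes, X-linked long noncoding RNA loci, X inactivation factors, markers of neural stem cells, neurons, astrocytes, oligodendrocytes, microglia and mesenchyme, p53 targets, interferon-stimulated genes, cell cycle and stress response. A list of YAP and TAZ targets was added after seeing the data. The Cast share of X-linked counts has a Wilson 95% interval per library. Its group means were compared by an exact two-sided permutation test that ignores the pairing of lines and whose smallest p is 0.33. Genes read from the inactive X needed at least 20 allele-assigned counts in every library and a Cast share of at least 10% in both libraries of a group. Background shares came from autosomal windows of 10 Mb with at least 1000 allele-assigned counts and under 1% Cast in the libraries of a line, and for the test of 129 reads taken for Cast from windows chosen in the control library alone.

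Genes were named by a rule fixed beforehand. After Smchd1 and Xist, it took the called genes of each comparison whose groups do not overlap, up to 10 with the largest rise and 10 with the largest fall, with an average log2 CPM of at least 1 (allelic tests, 0). From each list it took the called members, up to 6, or the 2 with the highest mean count if none was called. Where fewer than 5 genes passed, the 5 with the lowest p were added as values. The rule was applied to the fit without and to the fit with line as a block. Some genes that it took are not reported here, in text or figures. Genes at over 80% Cast, genes that passed the 10% share in 1 group, single members such as Ifit1, and known escape genes given as shares were chosen after their values were seen.

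Each test was checked on simulated counts with the mean of each line, the real library sizes and 200 changed genes of any chromosome, 100 each at 2-fold and 4-fold. Dispersions were those estimated with line as a block, and for the ratio those of the 129 counts divided by a fixed 4. The simulation thus builds in the pairing of lines and cannot decide between the blocked and the unblocked fit. For total counts the unblocked fit recovered 1% and 53% with 0 calls among unchanged genes, and the blocked fit 84% and 97% with 49. For Cast counts these were 0% and 0% with 0, and 25% and 67% with 0. For 129 counts they were 0% and 0% with 0, and 86% and 95% with 23. For the ratio they were 0% and 0% with 0, and 66% and 88% with 4. Alternatives were median-ratio size factors, DESeq2 1.42.0, no count filter, scaling from autosomes, own scaling of allele columns, the sum of the allele columns as total, leaving out each library, other thresholds for shares, an estimated correlation and fry for lists, and, chosen after seeing the data, the block combined with these, X-linked genes alone and exact tests within lines. Shares and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.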

Results

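The series profiled RNA from female mouse neural stem cells in which Smchd1, a chromatin protein needed for silencing of the inactive X chromosome and of some imprinted and clustered genes, was either present or deleted. Lines came from E14.5 embryos with 1 deleted and 1 conditional Smchd1 allele. The maternal X was of 129 origin and carried an Xist allele that cannot silence, and the paternal X was of Castaneus (Cast) origin, so the Cast X is the inactive X in the cells. Each line was divided, and part of it was given Cre recombinase by retrovirus, selected with puromycin and harvested 7 days later, while the rest stayed untransduced as the control. The comparison is therefore of deleted, transduced, puromycin-selected cells with undeleted, untransduced cells of the same lines. The data held 4 libraries from 2 lines, called A and B here, with 1 deleted and 1 control library of each line and so 2 libraries per group. The total count per library was 29873400 (control A), 34018500 (control B), 33572648 (deleted A) and 31823877 (deleted B), of which 25.3% to 25.9% were assigned to a parental genome.

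Smchd1 (chromosome 17, 71344489 to 71475343, mm10) had 2779 and 3461 counts in the control libraries of lines A and B and 785 and 852 in the deleted ones. Its log2 fold change was −1.96 (SE 0.12), with an edgeR adjusted p of 0.342 without a term for line and 0.0195 with line as a block. The count covers the whole gene, so transcripts that lack only the deleted part would still be counted. Xist (chromosome X, 103460375 to 103483217), the RNA that coats the inactive X, had 53514 and 75662 counts in controls and 72142 and 85511 in deleted cells (log2 fold change 0.26, SE 0.18, edgeR adjusted p = 0.601, and 0.11 with line as a block). Between 99.6% and 99.7% of its allele-assigned counts were Cast in every library.

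The inactive X was read slightly more in deleted cells. The Cast share of X-linked allele-assigned counts, Xist left out, was 4.83% in control A (Wilson 95% interval 4.74 to 4.93) and 4.63% (4.54 to 4.71) in control B, against 5.67% (5.57 to 5.77) in deleted A and 5.64% (5.54 to 5.74) in deleted B. Deleted libraries had a mean of 5.65% ± 0.0219 (SD, n = 2) and control libraries 4.73% ± 0.145 (SD, n = 2), a difference of 0.926 percentage points (exact two-sided permutation p = 0.33, the smallest that 2 against 2 allows). That test takes no account of the pairing of lines. Paired within lines, the differences were 0.839 and 1.01 points. Without Gpm6b, a gene left out after its values were seen, the difference was 0.640 points. Without Xist and its antisense gene Tsix, whose reads cannot be told apart from those of Xist if strand was not used, the shares were 4.32% and 4.07% in controls and 5.13% and 4.99% in deleted cells. As the background, autosomal windows under 1% Cast in the libraries of a line were taken to carry no Cast haplotype. They gave 0.372% and 0.330% Cast in the controls of lines A and B and 0.357% and 0.314% in the deleted libraries. The limit of 1% leaves out windows with more misassigned reads, so this background may be too low. Intervals and floors cover counting error only.

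**Figure D1:**
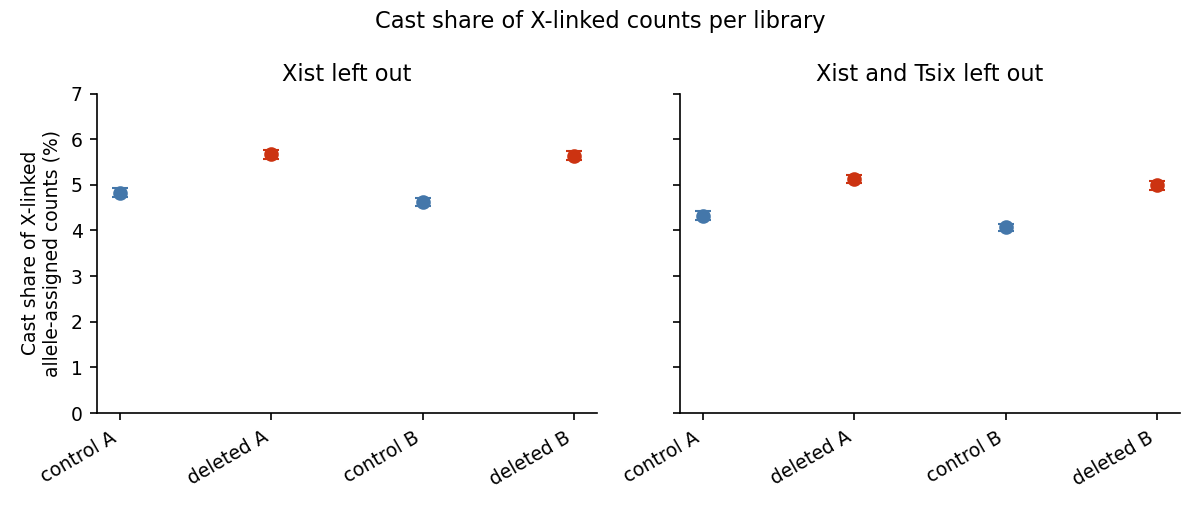
Cast share of X-linked allele-assigned counts (%) in each library, without Xist (left) and without Xist and Tsix (right), with Wilson 95% intervals as bars, controls in blue and deleted libraries in red. In each line the deleted library lies above its control, by 0.839 points in line A and 1.01 points in line B with Xist left out.

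On the Cast allele, 250 of all 7918 tested genes rose and 136 fell with line as a block. Of the 86 tested X-linked genes, 15 rose and 1 fell. They included Gpm6b, a neural membrane proteolipid (166238911 to 166388988), at 285 and 174 Cast counts in controls and 1220 and 1067 in deleted cells (log2 fold change 2.28, SE 0.14, edgeR adjusted p = 3.72e-11), and Eda2r, a receptor for ectodysplasin (97333840 to 97377216), at 195 and 220 against 561 and 560 (1.38, SE 0.14, edgeR adjusted p = 8.57e-08). The Cast share of Gpm6b went from 2.76% and 1.47% to 7.38% and 7.68%, and that of Eda2r from 10.8% and 10.9% to 21.3% and 25.3%. The apelin gene Apln rose by a log2 fold change of 3.01 (SE 0.42), Maged1 by 2.86, Nkap by 2.63, Igbp1 by 2.09, Atp6ap2 by 1.96, the mitophagy receptor gene Fundc1 by 1.78 and Tmem47 by 1.75. Klhl13 (23219271 to 23365082) had 2 and 0 Cast counts in controls and 14 and 14 in deleted cells. With controls set to a floor of 3 counts per library, its Cast counts were 4.51-fold higher. Apln and Maged1 stayed low, at 1.53% and 1.01% and at 1.17% and 0.280% Cast in deleted cells, the last of these below the autosomal background. Acsl4 fell by 0.80 (SE 0.23), but its 129 counts fell as well, as given below. Its Cast share was 8.67% and 6.2% in controls and 8.16% and 6.32% in deleted cells. Among the 15 rises, that of Mageh1 (0.395) was matched on the 129 allele (0.465). For these genes the Cast change is thus not particular to the inactive X.

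Without a term for line, edgeR called 0 X-linked genes on the Cast allele (3 higher and 0 lower at an unadjusted p under 0.05, and 0 with DESeq2). Among the lowest p-values there were those of Eda2r, Gpm6b, Tmem47 and Nkap, each with an adjusted p of 1. In counts simulated with the pairing of lines built in, that fit recovered 0 of 100 genes changed by 4-fold, against 67 with line as a block. With line as a block, adjusted over the X-linked genes alone, 21 rose and 2 fell, while DESeq2 with the same block called 3. The unblocked edgeR fit over all genes had a dispersion of 4.37. Fitted to the X-linked genes alone, a choice made after seeing the data, it had one of 0.0749. That fit called 1 gene higher, with 16 higher and 1 lower at an unadjusted p under 0.05.

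**Figure D2:**
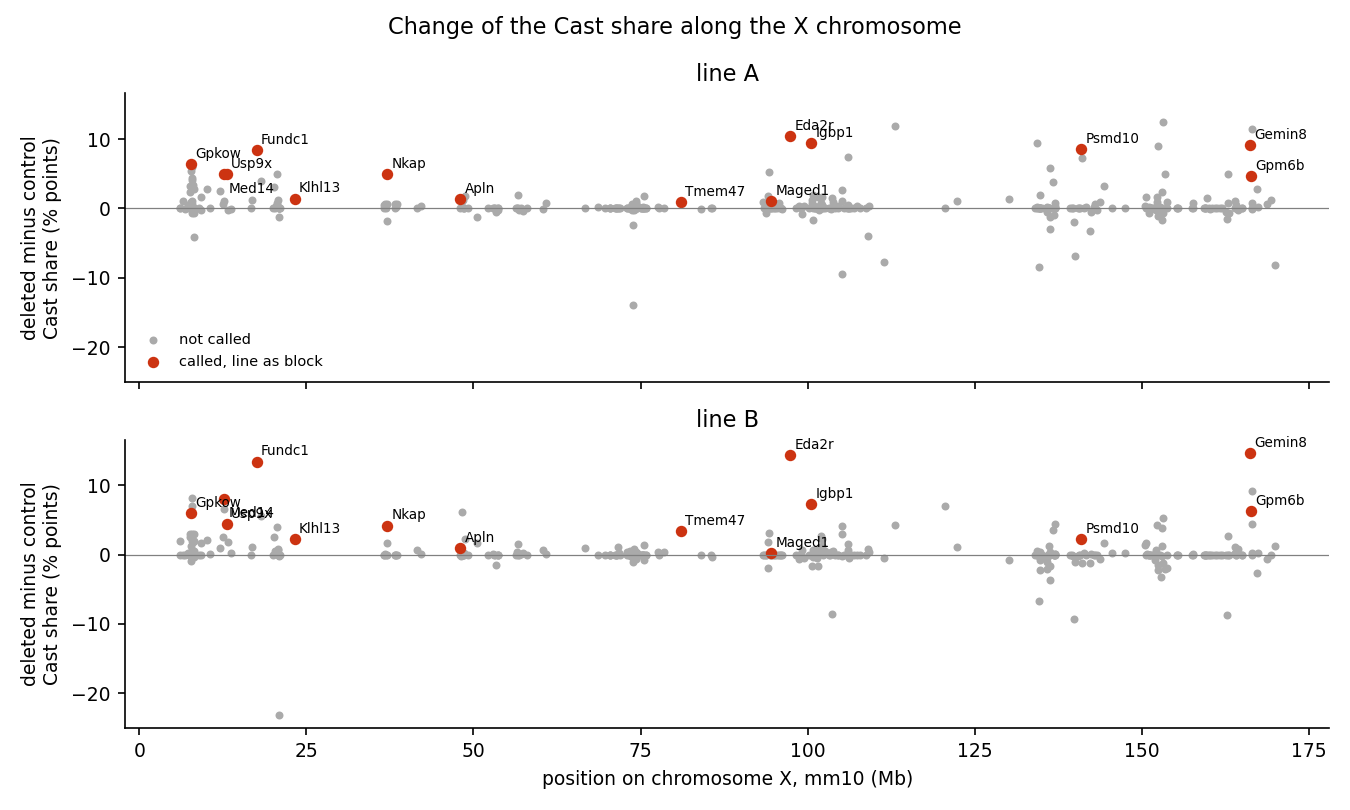
Difference in Cast share (deleted minus control, percentage points) of X-linked genes with at least 20 allele-assigned counts in every library, by position on chromosome X (mm10, Mb), for lines A and B. Named red points are genes whose Cast to 129 ratio was called higher with line as a block, such as Eda2r, which went from 10.8% to 21.3% in line A.

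The Cast to 129 ratio tests each allele against the other within a library. With line as a block, the ratio rose at 15 of 421 tested X-linked genes and fell at 0, and it rose at 23 adjusted over the X-linked genes alone. DESeq2 with the same block called 4 X-linked rises, and 7 adjusted over the X-linked genes alone. Besides Klhl13, Maged1, Apln, Nkap, Igbp1, Fundc1 and Tmem47, the ratio rose for Gpm6b by a log2 of 1.94 (SE 0.07, but 1.49 in line A and 2.48 in line B, a gap the SE does not cover). It also rose for Psmd10, a proteasome assembly chaperone gene, which had 0 Cast counts in both controls and 13 and 4 in deleted cells. With controls set to the same floor, the Cast counts of Psmd10 were 2.74-fold higher. Over all 12774 genes tested, 29 ratios rose and 8 fell with the block. Of these calls 6, all autosomal, moved in opposite directions in the lines. The falls included Lynx1 by 1.78 (SE 0.36), Tuba1a by 0.45 and Cdh13 by 0.34. Fisher's exact test of the allele counts within each line, chosen after seeing the data and covering counting error only, called 11 genes higher and 3 lower in both lines, 7 of the higher ones X-linked.

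Without a term for line, edgeR fitted to the X-linked genes alone, a choice made after seeing the data, called 0 ratios. There 25 were higher and 0 lower at an unadjusted p under 0.05 (dispersion 0.0343). Over all genes and without that term, 0 ratios were called by edgeR (28 higher and 15 lower at an unadjusted p under 0.05, dispersion 2.39) and 0 by DESeq2. Among the lowest p-values were those of Trrap (3 and 3 Cast counts in controls, 0 and 0 in deleted cells), Cox6a1 (0 and 0 against 4 and 3), Pim2 (0 and 0 against 5 and 7) and Gpm6b, each with an adjusted p of 1.

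On the 129 allele, that of the active X, changes went both ways. With line as a block, 27 of 414 tested X-linked genes rose and 15 fell, while DESeq2 with the same block called 5 higher and 5 lower. Over all 12528 genes tested on this allele the blocked edgeR fit called 844 higher and 464 lower, a share close to that of the X. These changes are thus not particular to the X. Egfl6 rose by a log2 fold change of 2.48 (SE 0.44), Tceal3 by 1.89, the protocadherin gene Pcdh11x by 1.31, Tspan7 by 1.14, Fam70a by 1.04, Nap1l3 by 0.99, the polyamine acetyltransferase gene Sat1 by 0.86, the creatine transporter gene Slc6a8 by 0.76, Xk by 0.73 and RP23-440J15.7 by 0.68. Phex fell by 1.64 (SE 0.32), Eda by 1.49, Nsdhl by 0.95, Acot9 by 0.94, Ebp by 0.82, Acsl4 by 0.75, Ndp by 0.64, Hprt by 0.62, Pak3 by 0.52 and the filamin gene Flna by 0.48. Nsdhl and Ebp encode enzymes of sterol synthesis. Without the block, edgeR called 0 (10 higher and 6 lower at an unadjusted p under 0.05, and 0 with DESeq2), with the lowest p for Tceal3, Tspan7, Slc6a8, Egfl6 and Phex.

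Genes read from the inactive X were largely shared between the groups. Of 370 X-linked genes with at least 20 allele-assigned counts in every library, 41 had a Cast share of at least 10% in both controls and 45 in both deleted libraries, with 39 in common. The 6 that reached it in both deleted libraries but not in both controls were 1810030O07Rik, Alg13, Fundc1, Gemin8, Gpkow and Ofd1. Of these 1810030O07Rik was at 12.9% in control A and 6.45% in control B, and Alg13 and Gemin8 were at 9.55% to 9.70% in controls. Those that reached it in both controls but not in both deleted libraries were Morc4 and Nono, the latter between 9.92% and 10.4% in every library. Among known escape genes the shares were 25.3% to 27.5% for the RNA helicase gene Ddx3x, 27.6% to 35.3% for the histone demethylase gene Kdm5c and 54.0% to 59.2% for Eif2s3x over the 4 libraries. More variable shares included those of Mid1 (30.7% and 22.6% in control and deleted A, 13.6% and 14.9% in B) and B230206F22Rik (39.1% and 40.6% in A, 33.6% in control B and lower in deleted B), and Car5b and Shroom4 were at 0% to 1.0%. Over the 370 genes the Cast share was higher in the deleted library of both lines for 93 genes and lower in both for 24, and 120 had no Cast count in any library. In 10 of the genes, Tsix, Rpl39, Hmgn5, Diap2, Tmem35, Gla, Bex4, Bex1, Morf4l2 and C330007P06Rik, over 80% of counts were Cast in every library. Without these 10, chosen after seeing the data, 31 genes reached 10% in controls and 35 in deleted cells.

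In total expression, 550 of 14860 tested genes rose and 281 fell with line as a block. The largest rises were of Trim30a by a log2 fold change of 5.20 (SE 0.36) and Ifi44 by 4.46 (SE 0.32), both known as interferon-inducible, followed by Stk32b by 3.38, the sialyltransferase gene St6gal2 by 3.29, Rimbp2 by 2.97, the phosphodiesterase gene Pde11a by 2.86, Scrg1 by 2.83, the postsynaptic scaffold gene Dlgap1 by 2.82, Fam20a by 2.82 and Gsg1l by 2.79. Trim30a had 20 and 0 counts in controls, 780 in deleted A and 30 in deleted B. The periplakin gene Ppl fell by 3.44 (SE 0.21), the synaptotagmin gene Syt13 by 3.33, Pde1a by 2.78, the hepatocyte growth factor receptor gene Met by 2.37, Ahnak by 2.30, Emp1 by 2.11, Rgs8 by 2.00, Smchd1 by 1.96 and the serotonin receptor gene Htr1b by 1.92.

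Without a term for line, edgeR called 0 genes (1018 higher and 719 lower at an unadjusted p under 0.05), while DESeq2 called 242 higher and 101 lower. The lowest p-values were those of Smchd1, Svep1 (log2 fold change 2.04), Ppp1r1a (−1.22), Fam55d (1.33) and Arl4c (−1.09), each with an adjusted p of 0.342. Counts of this comparison were simulated with the pairing of lines built in. There the blocked fit recovered 84 of 100 genes changed by 2-fold and made 49 calls among the unchanged genes, a larger false share than its 5% threshold. The unblocked fit recovered 1 and made 0.

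Astrocyte markers were higher in deleted cells of both lines. All 8 tested markers had positive fold changes, with a median log2 of 1.02 (camera adjusted p = 2.02e-07 with a preset correlation, and adjusted p = 0.316 with an estimated correlation). With line as a block (camera adjusted p = 8.83e-11), 5 of the 8 rose, the calcium-binding protein gene S100b by 2.64 (SE 0.28), the water channel gene Aqp4 by 2.01 (SE 0.16), the intermediate filament gene Gfap by 1.38 (SE 0.22), the gap junction gene Gja1 by 0.64 and Aldh1l1 by 0.62, and all 8 rose adjusted over the list alone. Over all genes Glul (0.21) and Aldoc (0.66) were not called. Without the block 0 of 8 were called over all genes and 3 adjusted over the list alone. Leaving out deleted A gave Aldh1l1 a value of −0.15.

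Interferon-stimulated genes were raised mainly in deleted A. Ifit1 had 25 and 17 counts in controls, 996 in deleted A and 24 in deleted B. Over the 24 tested members the median log2 fold change was 2.68 in line A and 0.16 in line B, with 24 and 18 members positive. Outside the list, Ifi44 went from 31 to 898 counts in line A and from 4 to 39 in line B. Camera gave the list an adjusted p of 9.24e-05 (median 1.98), adjusted p = 0.863 with an estimated correlation, and adjusted p = 0.000137 with line as a block. No member was called over all genes in either fit, B2m (1.21) included, and adjusted over the list alone 0 were called without the block and 10 rose with it. Without deleted A the median was −0.095 (camera adjusted p = 0.48).

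Cell cycle genes had small positive fold changes at all 24 tested members over both lines (16 of 24 in line A, median 0.08, and 24 in line B, median 0.30; overall median 0.19, camera adjusted p = 0.00017, and adjusted p = 0.748 with an estimated correlation). With line as a block (camera adjusted p = 0.00251) no member was called over all genes and 4 rose adjusted over the list alone. Top2a (0.44) and Mki67 (0.38) were not called. The list lost its call without control B (adjusted p = 0.102) and without deleted B (adjusted p = 0.251). Protocadherin beta genes, a cluster of cell adhesion genes known to respond to Smchd1, had a median of 0.41 over 21 tested members, 17 of them positive (0.71 in line A, 18 positive, and 0.10 in line B, 14 positive; camera adjusted p = 0.000521, adjusted p = 0.863 with an estimated correlation, and adjusted p = 0.00873 with line as a block). Pcdhb11 rose with the block (1.33, SE 0.16), 6 rose adjusted over the list alone, and Pcdhb19 (−0.13) and Pcdhb22 (0.06) were not called. This list lost its call without control A (adjusted p = 0.0523) or deleted A (adjusted p = 0.0537). In the protocadherin alpha and gamma clusters 1 gene each was tested, Pcdhac1, which rose with the block (0.70, SE 0.07), and Pcdhga11, which was not called (0.31). The counts of neighbouring protocadherins that share exons are uncertain.

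Imprinted genes changed in both directions. Of 36 tested members outside the Snrpn and Igf2r clusters, 5 rose and 2 fell with line as a block, and 8 rose and 5 fell adjusted over the list alone. Sfmbt2 rose by 2.00 (SE 0.34), Zdbf2 by 1.41, Peg3 by 0.76, Herc3 by 0.52 and Cd81 by 0.44, while Grb10 fell by 0.76 (SE 0.07) and Inpp5f by 0.46. In fits without the block, Grb10 ran from −1.78 without deleted B to 0.213 without control B. The list as a whole was not called (camera adjusted p = 0.6), and Mest (−0.18) and Gnas (0.01) were not called. In the Snrpn cluster Ndn rose (0.58, SE 0.08), while Peg12 (−0.35) and Ube3a (−0.06) were not called (list adjusted p = 0.793 by camera). In the Igf2r cluster 2 genes were tested and not called, Igf2r (0.03) and its antisense RNA Airn (0.32). None of the 39 Hox genes passed the count filter, the largest count being 4, with Hoxa3 at 0, 4, 0 and 3 and Hoxb4 at 0, 2, 0 and 3 in the libraries in the order given for depth.

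The remaining lists, apart from all X-linked genes on the Cast allele, were not called by camera with the preset correlation over all 4 libraries. Neural stem cell markers had an adjusted p of 0.793, with a median of −0.01 where camera's direction was up. Among them the glutamate transporter gene Slc1a3 (0.96, SE 0.08) rose with line as a block, and Ccnd2 (0.18) and Vim (−0.25) were not called. Neuron markers (camera adjusted p = 0.797) held Syt1, which fell by 1.47 (SE 0.07), and Elavl3, which rose by 0.65 (SE 0.11) with the block, while Mtap2 (0.03) and Gap43 (0.09) were not called. Oligodendrocyte markers (camera adjusted p = 0.0643, but adjusted p = 0.0423 without control B and adjusted p = 0.0118 without deleted A) were positive at 6 of 6 tested members, Cnp (0.21) and Cspg4 (0.61) included, with 0 called. Of microglia markers 2 were tested, Csf1r (−0.11) and Cd68 (0.04), and of mesenchyme markers 2, Acta2 (−0.35) and Col1a1 (0.04), with 0 called. P53 targets had a camera adjusted p of 0.29, with a median of −0.069 that became −0.184 without deleted A. Among them Gdf15 rose by 0.87 (SE 0.14) and Trp53inp1 fell by 0.59 and Sesn2 by 0.39 with the block, and Ccng1 (−0.06) was not called. In fits without the block, Gdf15 ran from −0.259 without deleted B to 1.92 without control B. In the stress response list (camera adjusted p = 0.233), Psat1 fell by 0.50 and Sesn2 by 0.39 with the block, and Hspa5 (0.16) was not called. Factors of X inactivation (adjusted p = 0.305), with Hnrnpu (−0.02) and Atrx (−0.10), known escape genes (adjusted p = 0.5), with Ddx3x (0.01), and X-linked long noncoding RNA loci (adjusted p = 0.5), with 6720401G13Rik (0.44), had 0 members called in either fit. All X-linked genes together gave a camera adjusted p of 2.9e-11 on the Cast allele (86 genes, median 0.17), with adjusted p = 0.182 with an estimated correlation and adjusted p = 1.06e-05 with line as a block. That list lost its call without control B (adjusted p = 0.0885). The adjusted p was 0.5 for X-linked genes in total counts and 0.793 on the 129 allele.

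Libraries of the same line shared their mosaic of parental haplotypes. The Cast share of autosomes differed by a mean of 0.633 percentage points between the libraries of line A and 0.440 between those of line B, and by 16.4 to 16.9 points between lines. On chromosome 12 it was 1.18% and 1.14% in line A and 52.4% and 52.9% in line B. No autosome differed by more than 2.83 points within a line.

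**Figure D3:**
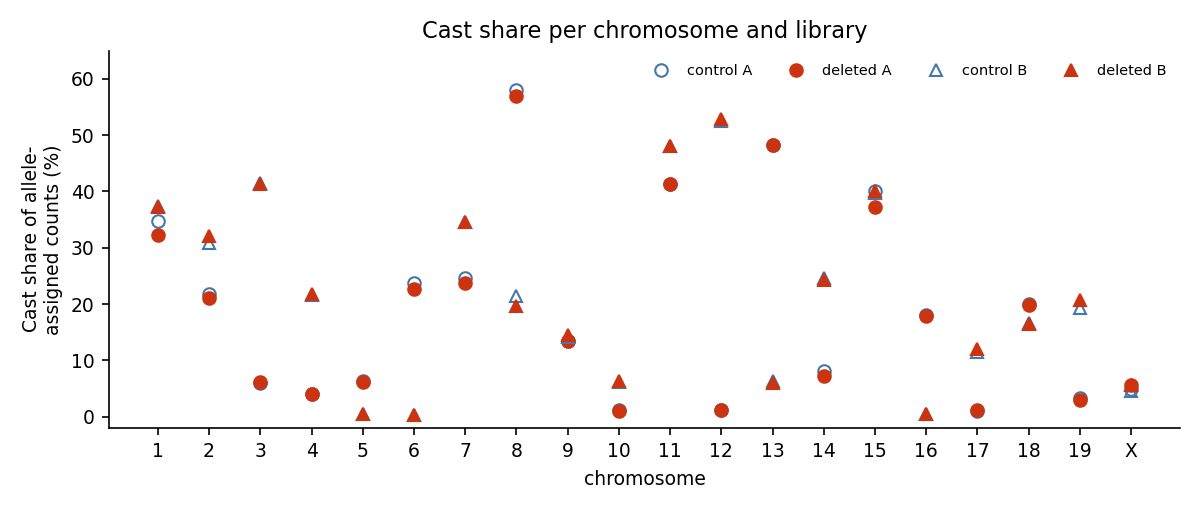
Cast share of allele-assigned counts (%) per chromosome in each library, circles for line A, triangles for line B, open for controls and filled for deleted cells. The lines differ on many chromosomes, such as 12 (1.18% against 52.4% in controls), while the control and deleted library of a line overlap.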

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

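The tests on the Cast reads of X-linked genes, on the interferon-stimulated genes and on a stretch of the active X were chosen after the results were seen. Those on strain variants and informative reads were chosen before, but the criterion applied to informative reads is not the one set then.

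The following results moved in opposite directions in the lines, a difference that was not tested. The median log2 fold change of neural stem cell markers was −0.084 in line A and 0.086 in line B, and that of neuron markers 0.217 and −0.15. The log2 Cast to 129 ratio changed by −0.235 and 1.295 for Actg1, by −1.665 and 0.871 for Gm20425, by −1.057 and 1.191 for Reln, by 0.561 and −0.609 for Cx3cl1, by −1.604 and 2.561 for Unc80 and by −0.328 and 2.257 for Rpl17, in lines A and B. All 6 genes were called with line as a block, and of them Gm20425 alone had at least 20 counts of both alleles in both lines.

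Cast reads of X-linked genes were higher in deleted cells. More 129 reads taken for Cast is argued against by autosomal windows chosen as without a Cast haplotype in the control alone, whose Cast share changed by −0.011 points (quartiles over windows within −0.0404 to 0.0218) where the X, without Xist and Tsix, changed by 0.864. Equally higher transcription of both X alleles would leave the Cast share as it was. As the whole cause it is argued against, in these 2 lines, by genes whose share changed in the same direction in both. Of 370 measured X-linked genes these were 117, and 79.49% of them were higher (Wilson 95% interval 71.29 to 85.81). That interval treats genes as independent, which genes of the same 4 libraries are not, so it covers no spread between cultures. A share of cells with the whole Cast X active, as the whole cause, is argued against by uneven rises. Of genes under 10% Cast in the control, with at least 1000 allele-assigned counts in both libraries and a Cast count in the other line, 56.67% of 30 in line A and 68.29% of 41 in line B rose by less than the pooled rise of these genes beyond counting error (37.9% and 32.5% without Gpm6b). A small share of such cells stays open. Loss of Smchd1 and transduction with puromycin cannot be told apart, since 0 groups hold both transduced and untransduced libraries.

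Interferon-stimulated genes were raised mainly in deleted A. Immune cells in that library are argued against by a summed count of 7 over 6 immune cell genes there (0 in its control). The 6 are the microglia list without Csf1r and Cd68, its 2 members with enough counts to be tested. Csf1r had 287 counts against 260, and Cd68 had a log2 fold change of 0.471 without deleted B, so the sum covers the 6 genes only. Loss of Smchd1, transduction and a response of the culture of line A alone stay open, as untested. In line B 18 of 24 members were positive, Ifi44 went from 4 to 39 counts and Trim30a from 0 to 30.

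The 10 X-linked genes with over 80% Cast in every library make up 2.703% of those measured. The median share of counts assigned to an allele was 16.1% (quartiles 9.41 to 23.6) for these genes and 21.4% for the others. The criterion set beforehand compared the medians alone, and it counted few informative reads out as the explanation. A stricter criterion on the quartiles was applied in its place, and by it the spread was too wide to decide. Few informative reads thus stay open for those of the genes with low shares. Strain variants that send active X reads to Cast cannot be told apart from expression of the inactive X, since 0.53% of genes in autosomal windows without Cast were read in this way and those windows are other stretches of other chromosomes. Of the 10 genes 6 lie within 10 Mb, against a median of 3 in 10000 random sets of measured X-linked genes (highest 8, permutation p = 0.005). A stretch of the active X from Cast is argued against by the 26 measured genes from the first to the last of these 6, of which 23.08% were at over 80% Cast, 17 at under 10% in every library and 3, Trmt2b, Hnrnph2 and Wbp5, between. A stretch from another strain, in lines whose strain is recorded as a mix, is a hypothesis that the clustering is consistent with, if such a strain shares the 129 bases at those 17 genes, which was not tested, and neither were reads shared between related genes.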

How the results depend on the processing

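The combinations with the block, X-linked genes alone, exact tests within lines and the shares without Tsix, Gpm6b or the 10 genes at high Cast were chosen after seeing the data. Calls depended mainly on the block. In total expression edgeR called 0 genes unblocked under median-ratio factors, no filter, autosomal scaling, summed alleles and every left-out library, but DESeq2 called 343. The paired fit, with line as a block, called 831, and 923 with median-ratio factors, 1194 with DESeq2, 1584 with no filter, 831 with autosomal scaling and 1223 with summed alleles. For X-linked Cast counts the block called 16 (18 with median-ratio factors, 3 with DESeq2, 19 with no filter, 16 with autosomal scaling, 11 with own scaling, 25 on X-linked genes alone), and X-linked genes alone without the block 1. For X-linked 129 counts the block called 42 (33, 10, 52, 43, 47 and 35 in the same order). For the ratio it called 37 (37, 4, 35, 37, 32 and 15), and exact tests in both lines, which cover counting error only, 14. Unblocked fits of X-linked Cast and 129 counts and of the ratio otherwise called 0 (DESeq2 called 5 changes of 129 counts outside the X). Unblocked edgeR over all genes did not recover simulated 4-fold allelic changes, so its zeros there say nothing about stability. The unblocked fits of X-linked genes alone, which called 0 ratios and 0 changes of 129 counts, were not simulated. The 5 called lists became 0 with an estimated correlation, with fry, and with the block and either of these, and 5 stayed called with the block alone. The other causes were not tested.

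The difference in X-linked Cast share stayed between 0.823 and 1.03 points with each library left out, was 0.864 without Xist and Tsix, 0.952 without escape genes and 0.952 without the 10 genes at high Cast, fell to 0.6401 without Xist and Gpm6b, and became 0.124 as a median over genes, where most genes had no or few Cast counts. Genes read from the inactive X numbered 57 in controls and 63 in deleted cells at 5%, 31 and 32 at 20%, 42 and 46 with a minimum of 10 counts, and 33 and 37 with 50.

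Directions turned for the following when a library was left out. The median of the interferon list, a called list, ran from −0.095 without deleted A to 2.84. Log2 fold changes ran from −0.008 to 0.551 for Pcdhga11, −0.134 to 0.007 for Ube3a, −0.233 to 0.351 for Igf2r, −0.687 to 1.30 for Airn, −0.04 to 0.049 for Gnas, −1.78 to 0.213 for Grb10, −0.055 to 0.065 for Ddx3x, −0.155 to 0.129 for Hnrnpu, −0.251 to 0.021 for Atrx, −0.66 to 0.055 for Vim, −0.063 to 0.133 for Mtap2, −0.499 to 0.501 for Gap43, −0.146 to 1.32 for Aldh1l1, −0.596 to 0.489 for Cd68, −1.22 to 0.187 for Acta2, −0.125 to 0.221 for Col1a1, −0.259 to 1.92 for Gdf15 and −0.323 to 1.92 for B2m. Grb10, Aldh1l1 and Gdf15 were called with the block, while the fits with a library left out had no block and held the lines in unequal numbers. Ddx3x was −0.003 with DESeq2, −0.058 with summed alleles, and with the block −0.003 and −0.059. With the block Gap43 was −0.001 with DESeq2 and −0.039 with summed alleles, and Cd68 −0.001 with median-ratio factors and −0.011 with DESeq2. The cause was not tested for these. A left-out library leaves 1 in its group, assumed to vary like the others, and with the block no residual degree of freedom remains, so no such fit was made.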

Other observations

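The tests of spans and of distance were chosen before their results were seen, and the list of YAP and TAZ targets after the falls had been seen.

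Autosomal genes were also called for allelic ratio. With line as a block 22 were called, 15 of them with at least 20 counts of both alleles in both lines, a set chosen after its values were seen. Not all of these changes were shared by the lines. The 6 genes flagged above as moving in opposite directions are among the 22, and Gm20425 is among the 15. Hspa8, also called, changed by a log2 ratio of −0.026 in line A and −1.249 in line B. The log2 Cast to 129 ratio rose by 1.89 and 0.75 in lines A and B for Rgs8, a regulator of G protein signalling whose total counts fell, by 0.93 and 0.53 for Aldoc, an astrocyte-enriched aldolase gene, by 0.69 and 0.35 for Rgs16 and by 0.42 and 0.16 for Sparc, an extracellular matrix protein gene. It fell by 1.88 and 1.51 for Lynx1, a modulator of nicotinic receptors, and by 0.40 and 0.48 for the tubulin gene Tuba1a.

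It was asked whether genes with a higher Cast to 129 ratio in deleted cells lie near genes that the inactive X expresses in controls. Eda2r (10.83% and 10.88% Cast in controls A and B) and Med14 (18.47% and 13.62%), both among the 15 genes, are such genes themselves. They were left out of the reference set, as were the genes flagged above for high Cast, which left 29. The median distance of the 15 genes to the nearest of these 29 was 1.009 Mb. In 10000 random sets matched on count the median was 0.913 Mb (0.331 to 3.839, permutation p = 0.5636). Proximity to other genes of this kind was thus not seen. It was also asked whether genes that rose in total expression have longer spans. Their median of 39.7 kb was 0.917 of that of genes that fell (43.3 kb), and both exceeded the 21.8 kb of all tested genes.

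A fall of YAP and TAZ targets is a hypothesis that the data leave open. The added list of 22 targets, 20 of them tested, gave a camera p of 0.0166 with line as a block and the preset correlation, and 0.233 with an estimated correlation, but 0.144 without the block, and 0.001 (without deleted A) to 0.985 (without control A) when a library was left out of that fit, with 11 members negative and 9 positive. With the block 4 members were called lower and 0 higher over all genes, and 7 lower and 1 higher over the list alone.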
